A study of Homo sapiens with 20 samples.

How the data were processed

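RNA from 4 breast cancer cell lines was compared on 20 two-colour Agilent 4x44K arrays, RNA labelled FOXA1 siRNA in 1 dye and RNA from the same line given a non-targeting siRNA (against firefly luciferase, per the labels' protocols) in the other. Per the labels' protocols, cells were transfected with 100 nM siRNA by lipid reagent in reduced-serum medium, MCF7 and MDA-MB-453 (MB453 here) grew in DMEM, T47D in RPMI and SKBR3 in McCoy's medium, all with serum, and total RNA was DNase-treated, amplified and labelled with Cy3 or Cy5. The protocols name 2 FOXA1 siRNAs without saying which went onto which array. Each line had 1 array at 36 h and, at 72 h, arrays numbered 1, 2 and 3 with the labelled FOXA1 siRNA RNA in Cy5 and a dye swap of number 1 with it in Cy3. The dye swap was read as the same RNA as array 1 because of its number, and the labels do not say so outright. Over genes above the negative controls, array 1 and its swap correlated at r = 0.90 in MCF7, 0.95 in T47D and 0.91 in MB453. In SKBR3 they correlated at only 0.62 (0.42 without the dye correction), so that reading is weakest there.

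The deposited scanner files hold the mean brightness of each spot and the median brightness of its local background, as an intensity on a linear scale in the green and red channels, written by Agilent Feature Extraction 9.5.1 from design 014850, per the file headers. Background subtraction was switched off in that software and dye normalization was applied to its processed signals, per the file headers. The deposited series matrix holds log10 ratios, which equal the log ratio of each scanner file with the sign turned on the dye swap arrays, so that their scale (log10), centring (none beyond the scanner software's) and direction (labelled FOXA1 siRNA over non-targeting) are known. Its column medians lay between -0.00383 and 0.0088. Probe coordinates are on build hg17, per the file headers. How the submitters tested for changes is not given in the sources used here.

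From the mean and background signals, the background was corrected with normexp (offset 50) and each array normalised by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Spots marked as outliers by the scanner software (between 125 and 619 per array) were set to missing, saturated spots (at most 141 per array in red and 1 in green) were kept, and spots of 1 probe were averaged. Because 3 of the 4 arrays of a line at 72 h carry the labelled FOXA1 siRNA RNA in Cy5, a dye effect per probe, the mean over the 4 lines of the dye-dependent part of array 1 and its swap, was subtracted from each array (SD 0.083 over genes on the log2 scale, above 0.5 in 7 genes). Every comparison therefore shares this estimate. Signs were then turned to labelled FOXA1 siRNA over non-targeting siRNA, and array 1 was averaged with its swap. This gave 3 replicates per line at 72 h and 16 replicates with the 36 h arrays.

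Of 41000 probes, 26829 were named by a match of accession, symbol or synonym to the gene reference, and 1617 kept the file's own name. A further 12554 had no name and entered no count. The named probes cover 18845 genes, of which 130 lacked values on some array and 18715 were tested. A gene was represented by its probe with the highest mean brightness. Of 7137 genes with several probes, 0 had probes whose means over the 4 lines at 72 h went opposite ways by over 0.5 each. The filter chosen required a probe to be well above background in at least 1 channel on at least 4 of the 20 arrays, by the scanner software's flag. That flag was set on 100% of spots, negative controls included, so that filter, no filter and a demand for all 20 arrays differed by 0 probes and their comparison is void. A filter against the 95th percentile of the negative control spots was added after seeing the data and left 16364 genes. Median signals were between 1.61 and 2.92 times the negative control median in green and between 2.93 and 4.99 times in red, which limits precision for dim genes.

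Genes were tested with limma (lmFit, eBayes) on log2 ratios against 0, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The lines at 72 h, their mean, and the difference between MCF7 and T47D on one side and MB453 and SKBR3 on the other came from 1 fit of the 12 replicates with a mean per line (8 residual degrees of freedom). The 36 h mean and the difference between times came from a fit of 16 replicates with 8 groups (8 residual degrees of freedom), in which each lone 36 h array is assumed to vary like the 72 h replicates. Lines are fixed, so p-values cover only the spread between replicates. In all, 15 gene lists written from general knowledge were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were luminal, basal and mesenchymal markers, epithelial junction, oestrogen-induced, androgen and apocrine, S phase, G2 and mitosis, interferon response, NF-kB, hypoxia, unfolded protein and amino acid stress, cholesterol synthesis and p53 target genes, and markers of blood and vessel cells. TOX3, KDM4B, KRT6A, SNAI2, RRM1 and CMPK2 had no value, and XBP1, MYB, TFF1, CA12, GREB1, PGR and DHCR24 are each in 2 lists.

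The lists, tests, named-gene rule and first set of other settings were fixed before the data were examined. By that rule FOXA1 comes first. Each line names its 6 largest increases and 6 largest decreases past the threshold that moved 1 way on its 4 arrays at 72 h, leaving out LOC and clone names. The mean names the 10 largest each way with 1 sign on all 16 arrays at 72 h. The difference between receptor classes names 6 each way whose line means on 1 side lie beyond both of the other, and that between times names 5 each way with 1 sign in all 4 lines. Up to 4 members of a list with the largest changes past the threshold, and ESR1, GATA3, FOXA2, FOXA3, KRT8, KRT18, KRT5, KRT14, EGFR, ERBB2 and AR, could also be named.

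The settings fixed then were no background subtraction, Agilent's processed signals, the series matrix, median centring, no dye correction, dye swaps as separate replicates, a dye term with the swap pair as a random block, probes averaged per gene, a variance with trend and robust estimation, the replicate number as a block, slide as a random block, each line alone, only replicate 1 at 72 h, each replicate and each line left out, a 2-fold minimum, and an estimated correlation in camera. The settings added, chosen after seeing the data, were the negative control filter, leaving out the dye swaps, only array 1 at 72 h without its dye swap, and slide as a fixed block within the lines that share slides. On simulated data the fit recovered between 94% and 100% of changes of 0.5 (log2) and between 24% and 44% of changes of 0.25 in single lines. Genes were drawn independently there, with the spread pooled over lines, few changed genes and no slide effect. Changes of 0.5 were recovered in 100% of cases in the mean at 72 h and in the difference between receptor classes, and in 92% in the difference between times. Of the simulated calls, between 1.1% and 9% were false in single lines, 12% in the mean at 72 h, 7.1% between receptor classes, 1.7% between times and 17.4% in the mean at 36 h, each on 18715 genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Probes without a gene name, siRNA sequences and off-target matches were left out of the comparisons.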

Results

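Gene expression was measured in 4 established breast cancer cell lines given small interfering RNA (siRNA, a short duplex that directs the cleavage of a matching transcript) against FOXA1, a forkhead transcription factor of luminal breast cells. MCF7 and T47D are known to express the oestrogen receptor, and MDA-MB-453 (labelled MB453) and SKBR3 are known to lack it. Per its title, the series asks about FOXA1 as a repressor of basal breast cancer expression. Each array compared, in 2 dyes on the same spots, RNA from cells labelled FOXA1 siRNA with RNA from cells of the same line given a non-targeting siRNA. The 20 arrays comprised, in each line, 1 array at 36 h and 4 arrays at 72 h, of which 3 were numbered replicates and 1 was a dye swap of replicate 1, averaged with it. This left 3 replicates per line at 72 h (12 in all) and 1 per line at 36 h. The labels do not say that replicates were separate cultures. P-values therefore measure only the spread between these samples, which may be technical. Between 55.8% and 77.2% of spots per array were brighter than the negative control spots in the green channel and between 55.8% and 74.4% in the red. The number of arrays limits the precision. The tests covered 18715 genes. Every log2 change is the channel labelled FOXA1 siRNA over the non-targeting channel, with its standard error (SE).

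FOXA1 transcript was not lower in every line labelled FOXA1 siRNA. At 72 h FOXA1 was 0.40 ± 0.10 (log2, SE, n = 3) higher in MCF7, a 1.31-fold difference, with a limma adjusted p of 0.00786. In T47D FOXA1 measured 0.19 ± 0.10 (n = 3, limma adjusted p = 0.169), with replicate 2 at -0.10. FOXA1 fell in MB453, to -0.68 ± 0.10 (n = 3, limma adjusted p = 0.000419), a 1.61-fold decrease, and in SKBR3 it measured -0.32 ± 0.10 (n = 3, limma adjusted p = 0.0446). On the single arrays at 36 h FOXA1 measured 0.47 in MCF7, 0.48 in T47D, -0.31 in MB453 and -0.17 in SKBR3. These values come from probe A_24_P347431 (transcript NM_004496, chromosome 14, 37129205 to 37129264 on build hg17, per the file headers). A probe next to it, A_23_P37127 (chromosome 14, 37129297 to 37129356) was printed in 10 spots. It gave means at 72 h of 0.47, 0.28, -0.63 and -0.19 in MCF7, T47D, MB453 and SKBR3. No FOXA1 spot was saturated. The dye swap of each line had the sign of its partner array at A_24_P347431. Because the targeted transcript goes against the label in MCF7 and T47D, samples are called labelled FOXA1 siRNA throughout. The MCF7 call was lost without replicate 2 (0.34, limma adjusted p = 0.0682), and T47D passed without its replicate 2 (0.34, limma adjusted p = 0.0299). The SKBR3 call was lost without replicate 2 (-0.31, limma adjusted p = 0.185), without replicate 3 (-0.24, limma adjusted p = 0.303) and under 6 other settings.

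**Figure D1:**
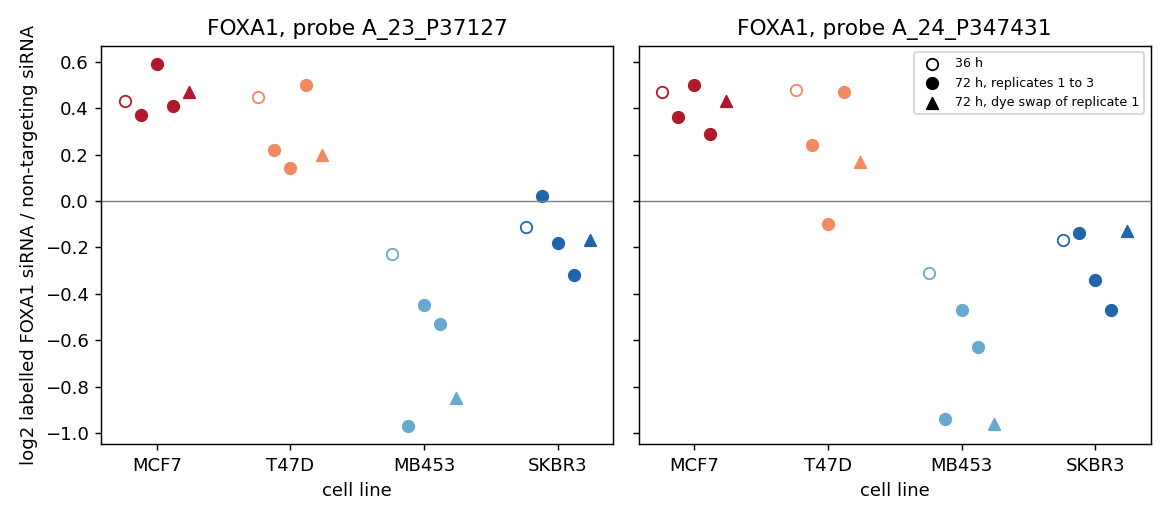
FOXA1 log2 ratio (labelled FOXA1 siRNA over non-targeting siRNA) on each of the 20 arrays, by line and time, for probes A_23_P37127 and A_24_P347431. At A_24_P347431 the replicates at 72 h averaged 0.40 in MCF7 and -0.68 in MB453.

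In MCF7 at 72 h, where FOXA1 itself was higher against its label, the RNA labelled FOXA1 siRNA held 10.7-fold more transcript of ANXA1, the gene of a calcium-dependent phospholipid-binding protein (log2 3.42 ± 0.33 SE, n = 3, limma adjusted p = 2.2e-06). GPNMB, a transmembrane glycoprotein, rose by 2.66 ± 0.09, the pseudokinase gene TRIB2 by 2.39 ± 0.07 and the monoamine oxidase gene MAOB by 2.38 ± 0.07. The keratin gene KRT23 rose by 2.12 ± 0.18 and ARHGAP18, a regulator of Rho GTPases, by 2.03 ± 0.10. TYMS, the thymidylate synthase of DNA precursor supply, fell by 2.68 ± 0.09 and the aldehyde oxidase gene AOX1 by 2.66 ± 0.16. Among the largest decreases, the cytokinesis gene CEP55 fell by 2.54 ± 0.09 and the Rac exchange factor gene PREX1 by 2.48 ± 0.13. The histone genes H4C13 and H4C2 fell by 2.72 ± 0.27 and 2.59 ± 0.27, although near-identical histone H4 copies may share these probes. ESR1, the oestrogen receptor gene, fell by 1.52 ± 0.07.

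Cell cycle genes fell together in MCF7 labelled FOXA1 siRNA. All 35 measured S phase genes fell (35 also adjusted over the list alone; camera adjusted p = 1.75e-27), among them RAD51 (-2.34), TK1 (-2.22) and CDC45 (-2.20). Of 36 G2 and mitosis genes 35 fell (35 adjusted over the list alone; camera adjusted p = 1.74e-28), among them ASPM (-2.33) and HMMR (-2.19). Of 35 oestrogen-induced genes, 26 fell and 2 rose (29 and 2 adjusted over the list alone; camera adjusted p = 2.01e-12). XBP1 fell by 2.16, MYB by 2.0, EGR3 by 1.97 and AREG by 1.85. Among 28 luminal markers 18 fell and 6 rose (18 and 6 adjusted over the list alone; camera adjusted p = 0.000191). RERG (-2.0) and AGR3 (-1.68) were among the lower and KRT18 (0.57) and KRT8 (0.40) among the higher. Basal markers rose more often than they fell, 12 against 2 of 39 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.475 with an estimated correlation). ANXA1 and the laminin gene LAMB3 (1.78) led them. Epithelial junction genes gave 14 that rose and 2 that fell of 28 (15 and 3 adjusted over the list alone; camera adjusted p = 0.0038, adjusted p = 0.0609 with an estimated correlation). CLDN3 measured 1.19, ESRP2 -0.84 and the E-cadherin gene CDH1 -0.71. Of 20 p53 target genes 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00125), including TP53INP1 (1.91) and CCNG1 (1.28). With an estimated correlation, camera adjusted p-values were 0.0372 for S phase, 0.0464 for G2 and mitosis and 0.0146 for oestrogen-induced genes. They were 0.0464 for luminal markers and 0.0365 for p53 targets. In all, 7204 genes passed, 3506 higher and 3698 lower, of which 547 differed by at least 2-fold. Median centring in place of loess gave 4136 genes with 64.5% higher against 48.7%. It ended the luminal list call (adjusted p = 0.0591) and the CDH1 call (-0.17).

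T47D at 72 h, where FOXA1 did not pass the test and measured above 0, showed 9.60-fold more of the chemokine receptor transcript CX3CR1 in RNA labelled FOXA1 siRNA (log2 3.26 ± 0.12 SE, n = 3, limma adjusted p = 3.08e-09). ANXA1 rose by 2.74 ± 0.33, the lysosomal membrane gene LAMP3 by 2.43 ± 0.35, the lipogenic gene THRSP by 2.40 ± 0.12, SYPL1 by 2.21 ± 0.13 and N4BP2L1 by 2.16 ± 0.09. TYMS fell by 2.42 ± 0.09, SUSD3 by 2.17 ± 0.17, the neuropeptide gene NMU by 2.14 ± 0.12 and LRRN3 by 2.13 ± 0.06. The thyroid hormone-binding crystallin gene CRYM fell by 2.05 ± 0.18 and the Wnt pathway transcription factor gene LEF1 by 2.05 ± 0.09. ESR1 fell by 0.98 ± 0.07 and AR, the androgen receptor gene, by 0.93 ± 0.06.

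All 35 S phase genes fell in T47D labelled FOXA1 siRNA (35 adjusted over the list alone; camera adjusted p = 3.51e-19, adjusted p = 0.0848 with an estimated correlation). So did 35 of 36 G2 and mitosis genes (36 adjusted over the list alone; camera adjusted p = 5.64e-19, adjusted p = 0.116 with an estimated correlation). Oestrogen-induced genes fell in 24 of 35 cases and rose in 2 (24 and 3 adjusted over the list alone; camera adjusted p = 5.11e-08, adjusted p = 0.0597 with an estimated correlation). PDZK1 fell by 1.88 and CXCL12 by 1.79. Epithelial junction genes rose in 17 and fell in 3 of 28 cases (18 and 4 adjusted over the list alone; camera adjusted p = 0.00347, adjusted p = 0.0848 with an estimated correlation). Of 36 interferon response genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 0.00168, adjusted p = 0.656 with an estimated correlation). They included the antiviral genes XAF1 (1.22), RSAD2 (0.90) and OASL (0.86). NF-kB genes rose in 10 and fell in 1 of 25 cases (13 and 1 adjusted over the list alone; camera adjusted p = 0.00347, adjusted p = 0.568 with an estimated correlation). The cytokine genes CCL5 and TNF rose by 1.26 and 0.84. Of 20 p53 target genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00347, adjusted p = 0.0663 with an estimated correlation). Luminal markers fell in 14 and rose in 4 of 28 cases (14 and 4 adjusted over the list alone; camera adjusted p = 0.0229, adjusted p = 0.216 with an estimated correlation), led by MYB (-1.72), AGR3 (-1.65) and TFF1 (-1.31). Of 39 basal markers 9 rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.173), CD44 (-0.62) among the latter. The test called 7666 genes, 3567 higher and 4099 lower, 402 of them by at least 2-fold. Median centring gave 3336 (36.4% higher against 46.5%). Without replicate 3 the interferon call was lost (adjusted p = 0.0568), as were those of XAF1 (0.78), RSAD2 (0.60) and OASL (0.57). The XAF1 call was also lost without replicate 1 (1.36, limma adjusted p = 0.0665) and with a robust variance (1.22, limma adjusted p = 0.0886), and that of CD44 under median centring (-0.38). The luminal call was lost under median centring (adjusted p = 0.131), without the dye correction (adjusted p = 0.0627) and with probes averaged per gene (adjusted p = 0.0556).

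MB453 at 72 h, where FOXA1 fell, carried 5.40-fold more BBOX1, the last enzyme of carnitine synthesis, in RNA labelled FOXA1 siRNA (log2 2.43 ± 0.10 SE, n = 3, limma adjusted p = 1.84e-08). ANXA1 rose by 2.15 ± 0.33, CX3CR1 by 2.15 ± 0.12, and the calprotectin gene S100A8 by 2.06 ± 0.18. The lactoferrin gene LTF rose by 1.96 ± 0.07 and the glucuronosyltransferase gene UGT1A6, which shares exons with its neighbours, by 1.95 ± 0.12. SOCS2, a suppressor of cytokine signalling, fell by 1.48 ± 0.06, PAQR5 by 1.37 ± 0.09, the sphingomyelinase gene SMPD3 by 1.37 ± 0.24 and the chemokine receptor gene ACKR3 by 1.35 ± 0.09. The interferon-induced genes IFI44L and IFIT2 fell by 1.37 ± 0.32 and 1.40 ± 0.47, with limma adjusted p-values of 0.0073 and 0.0498. AR rose by 0.30 ± 0.06, and the apocrine secretory gene PIP fell by 0.89 ± 0.11.

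Of 39 basal markers in MB453 labelled FOXA1 siRNA, 13 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 0.000346, adjusted p = 0.687 with an estimated correlation). The keratin gene KRT16 rose by 1.58 and the laminin genes LAMB3 and LAMC2 by 1.31 and 0.87. The basal median of 0.121 became 0.01 with median centring, with the call kept. S phase genes fell in 20 of 35 cases (27 adjusted over the list alone) and G2 and mitosis genes in 20 of 36 (28 adjusted over the list alone). Each list had a camera adjusted p of 2.01e-10 and an adjusted p = 0.687 with an estimated correlation. The G2 and mitosis median was -0.546 on array 1 and -0.479 on its swap, against -0.219 on array 2 and -0.187 on array 3. The S phase median was -0.453, -0.372, -0.24 and -0.262 in the same order. Without replicate 1 the G2 and mitosis median of -0.313 became -0.193. TK1 fell by 0.76, TYMS by 0.70 and FOXM1 by 0.68. Interferon response genes fell in 6 of 36 cases (5 adjusted over the list alone; camera adjusted p = 0.000333, adjusted p = 0.938 with an estimated correlation). HERC5 fell by 1.15 and RSAD2 by 0.95. Luminal markers went both ways, with 4 higher and 4 lower of 28 (4 and 4 adjusted over the list alone; camera adjusted p = 0.907). There were 4223 genes past the threshold, 2279 higher and 1944 lower, 95 of them by at least 2-fold. The count was 839 with median centring (39.8% higher against 54.0%), 2607 without replicate 2 and 2507 without replicate 3. Without replicate 2 the calls of IFIT2 (-1.12), IFI44L (-1.24), RSAD2 (-0.87) and AR (0.25) were lost. Those of IFIT2 and RSAD2 were also lost without replicate 3 (-1.19 and -0.85), with a robust variance and under median centring (-1.31 and -0.76). In all, the IFIT2 call was lost in 9 settings, with values between -1.41 and -1.12. The calls of PIP (-0.71) and AR (0.28) were lost under median centring, and that of AR without the dye correction (0.19).

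SKBR3 at 72 h, where the call of FOXA1 (-0.32) depended on the setting, held 5.54-fold more KRT23 in RNA labelled FOXA1 siRNA (log2 2.47 ± 0.18 SE, n = 3, limma adjusted p = 2.48e-06). The netrin receptor gene UNC5B rose by 1.98 ± 0.14, RNF141 by 1.92 ± 0.12, THRSP by 1.91 ± 0.12 and ANXA1 by 1.87 ± 0.33. PREX1 fell by 2.06 ± 0.13, TARP, which overlaps the T cell receptor gamma locus, by 1.69 ± 0.10, and the mitochondrial ribosome gene MRPL41 by 1.60 ± 0.09. ABHD10 fell by 1.59 ± 0.12, ATP8B2 by 1.46 ± 0.12 and the replicative helicase gene MCM6 by 1.40 ± 0.13. The potassium channel gene KCNH8 measured 2.45 ± 0.50 (limma adjusted p = 0.00383), but 0.00 without background subtraction and 0.02 from Agilent's processed signals.

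NF-kB genes rose in 13 of 25 cases and fell in 0 in SKBR3 labelled FOXA1 siRNA (16 and 0 adjusted over the list alone; camera adjusted p = 7.58e-08, adjusted p = 0.297 with an estimated correlation). The lipocalin gene LCN2 rose by 1.42, TNFAIP2 by 0.90, BIRC3 by 0.86 and RELB by 0.82. The list median was 0.136 on array 1 and 0.055 on its swap, against 0.321 on array 2 and 0.45 on array 3. Basal markers rose in 16 and fell in 1 of 39 cases (19 and 1 adjusted over the list alone; camera adjusted p = 6.62e-07, adjusted p = 0.297 with an estimated correlation). Their median was 0.098 on array 1 and 0.018 on its swap, against 0.262 on array 2 and 0.282 on array 3. Over genes above the negative controls replicate 1 correlated with replicates 2 and 3 at r = 0.51 and 0.52. Replicates 2 and 3, which shared a slide, correlated at 0.88. The keratin gene KRT6B rose by 1.77, the adhesion receptor gene CD44 by 1.16 and LAMB3 by 0.68. Cholesterol synthesis genes fell in 11 and rose in 1 of 25 cases (12 and 1 adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.297 with an estimated correlation), including MVK (-0.45), FDFT1 (-0.44) and DHCR7 (-0.44). S phase genes gave 7 lower and 1 higher of 35 (7 and 1 adjusted over the list alone; camera adjusted p = 0.131). Luminal markers gave 7 lower and 4 higher of 28 (7 and 4 adjusted over the list alone; camera adjusted p = 0.370). The count was 4101 genes, 1916 higher and 2185 lower, 78 of them by at least 2-fold. It was 931 with median centring (33.3% higher against 46.7%), 2112 with the line fitted alone, 1884 without replicate 2 and 1734 without replicate 3. Without either of these replicates the calls of BIRC3 (0.80 and 0.74) and RELB (0.84 and 0.74) were lost. BIRC3 was also lost with a robust variance (0.86, limma adjusted p = 0.0512), RELB under median centring (0.77), and KRT6B with the line fitted alone (limma adjusted p = 0.0586).

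Averaged over the 4 lines at 72 h, ANXA1 was 5.84-fold higher in RNA labelled FOXA1 siRNA (log2 2.55 ± 0.16 SE, 12 replicates, higher on all 16 arrays, limma adjusted p = 3.4e-08). The mean of FOXA1 itself, which differed in sign between lines, was -0.10 ± 0.05 (limma adjusted p = 0.11). CX3CR1 rose by 1.92 ± 0.06, SYPL1 by 1.62 ± 0.06, THRSP by 1.61 ± 0.06, RNF141 by 1.55 ± 0.06 and S100A8 by 1.55 ± 0.09. The cell cycle kinase gene CDK6 rose by 1.48 ± 0.06, ARHGAP18 by 1.40 ± 0.05, ARFIP1 by 1.29 ± 0.05 and the ribosomal protein paralogue gene RPS27L by 1.27 ± 0.07. PREX1 fell by 1.70 ± 0.07, TYMS by 1.62 ± 0.05, MCM6 by 1.40 ± 0.06, MRPL41 by 1.33 ± 0.05, and the thymidine kinase gene TK1 by 1.32 ± 0.08. The cyclin A gene CCNA2 fell by 1.27 ± 0.07, ATP8B2 by 1.26 ± 0.06, CDC45 by 1.24 ± 0.05, the androgen-metabolising gene UGT2B11, which has close paralogues, by 1.23 ± 0.05 and ABHD10 by 1.22 ± 0.06. The naming rule required these 20 genes to move 1 way on all 16 arrays at 72 h, which 916 higher and 1081 lower genes past the threshold did.

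**Figure D2:**
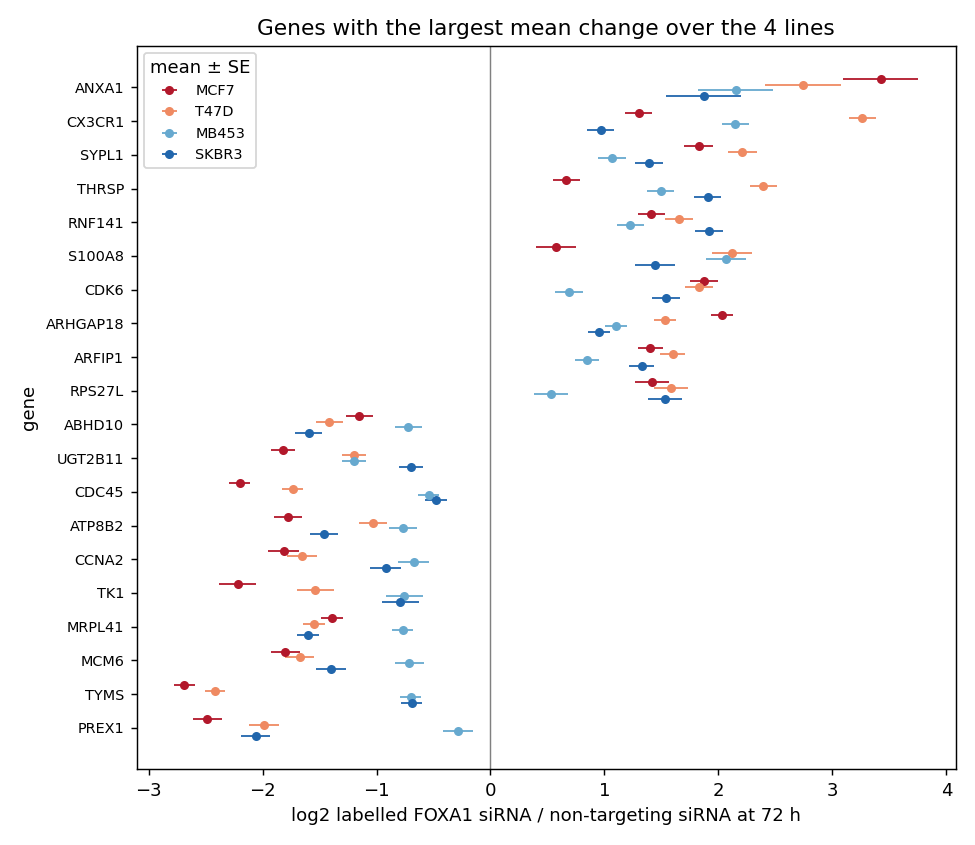
Log2 ratio at 72 h (labelled FOXA1 siRNA over non-targeting siRNA) of the 20 genes with the largest mean change, as the mean and SE of each line. Over the 4 lines ANXA1 averaged 2.55 and PREX1 averaged -1.70.

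Basal markers rose in the mean of the lines labelled FOXA1 siRNA in 25 of 39 cases and fell in 1 (26 and 1 adjusted over the list alone; camera adjusted p = 2.66e-05, adjusted p = 0.203 with an estimated correlation). The list median was 0.133. EGFR was the gene that fell (-0.10), and KRT14 did not pass (0.07, limma adjusted p = 0.228). KRT5 counted as higher (0.10), although its spots were not above the negative controls in MCF7, T47D or MB453. Luminal markers fell in 16 and rose in 5 of 28 cases (16 and 6 adjusted over the list alone; camera adjusted p = 0.00606, adjusted p = 0.114 with an estimated correlation). Oestrogen-induced genes fell in 24 and rose in 4 of 35 (26 and 4 adjusted over the list alone, camera adjusted p = 9.15e-07, adjusted p = 0.0883 with an estimated correlation). That list had no call in MB453 (8 higher and 4 lower, camera adjusted p = 0.770) or SKBR3 (5 higher and 8 lower, camera adjusted p = 0.366). S phase genes fell in 34 of 35 cases (35 adjusted over the list alone; camera adjusted p = 1.64e-19, adjusted p = 0.0883 with an estimated correlation). G2 and mitosis genes fell in 36 of 36 (36 adjusted over the list alone, camera adjusted p = 1.49e-19, adjusted p = 0.108 with an estimated correlation). In SKBR3 by itself only 3 of them fell and 1 rose (median -0.048, camera adjusted p = 0.751). Epithelial junction genes rose in 17 and fell in 5 of 28 (17 and 5 adjusted over the list alone; camera adjusted p = 0.00732, adjusted p = 0.108 with an estimated correlation). NF-kB genes rose in 15 and fell in 1 of 25 (15 and 1 adjusted over the list alone; camera adjusted p = 0.00482, adjusted p = 0.405 with an estimated correlation). Targets of p53 rose in 13 and fell in 4 of 20 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00727, adjusted p = 0.0883 with an estimated correlation). No call was made for mesenchymal markers (4 higher and 5 lower of 27, camera adjusted p = 0.847), androgen and apocrine genes (5 and 14 of 24, camera adjusted p = 0.154), or interferon response genes (6 and 3 of 36, camera adjusted p = 0.847). None was made either for hypoxia genes (2 and 10 of 20, camera adjusted p = 0.154), unfolded protein and amino acid stress genes (11 and 7 of 20, camera adjusted p = 0.228), cholesterol synthesis genes (4 and 12 of 25, camera adjusted p = 0.066) or markers of blood and vessel cells (2 and 3 of 20, camera adjusted p = 0.947). Adjusted over the list alone, these 7 lists gave 4 and 5, 5 and 14, 0 and 0, 2 and 10, 11 and 7, 4 and 12, and 2 and 2 genes in the same order.

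In all 9850 genes passed in the mean of the lines, 4813 higher and 5037 lower, 72 of them by at least 2-fold. In each of the 4 lines 490 genes were called higher and 536 lower. MCF7 and T47D shared 1975 higher and 2379 lower calls and had 367 opposite calls, where independent lists would give 668, 810 and 1473. MB453 and SKBR3 shared 770 and 830 and had 163 opposite calls, where independent lists would give 233, 227 and 465. The lines share 1 estimate of the spread per gene, so the lists are not independent. Part of the sharing can come from that, which was not tested. Across genes, which are not independent replicates and share 1 dye-effect estimate, Pearson's r of the line means was 0.64 between MCF7 and T47D and between 0.40 and 0.53 for the other 5 pairs of lines. Median centring gave 5786 genes (39.9% higher against 48.9%). Without MCF7 the calls of the luminal (adjusted p = 0.0548), junction (adjusted p = 0.0548) and p53 (adjusted p = 0.0554) lists were lost, as was the NF-kB call without SKBR3 (adjusted p = 0.107). FOXA1 passed in the mean without MCF7 (-0.27, limma adjusted p = 0.00467), without T47D (-0.20), without T47D replicate 3 (-0.14) and in the settings without a dye correction (-0.15) or with swaps as separate replicates (-0.11).

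The lines known to express the oestrogen receptor (MCF7 and T47D) differed from those known to lack it (MB453 and SKBR3) in MYBL1, a MYB-family transcription factor gene. Its change in RNA labelled FOXA1 siRNA differed by -2.10 ± 0.10 (log2, SE, 6 replicates a side from 2 lines, limma adjusted p = 3.28e-08). Lines are fixed in this fit, so its p-values cover these lines and not receptor classes at large. FOXA1 itself differed by 0.79 ± 0.10 (limma adjusted p = 9.26e-05), being above 0 against its label in MCF7 and T47D. The calcitonin receptor gene CALCR differed by -1.97 ± 0.10, PHLDA1 by -1.93 ± 0.12, the scaffold gene PDZK1 by -1.90 ± 0.13, HMMR by -1.88 ± 0.10 and TYMS by -1.86 ± 0.09. On the other side stood GPNMB (1.40 ± 0.09), the natriuretic peptide receptor gene NPR3 (1.37 ± 0.10), the netrin gene NTN4 (1.33 ± 0.16), MAOB (1.22 ± 0.07), the growth factor-binding gene IGFBP3 (1.20 ± 0.12) and TNS3 (1.17 ± 0.11). ESR1 differed by -1.25 ± 0.07, with changes of -1.52 in MCF7 and -0.98 in T47D. Its spots were not above the negative controls in MB453 or SKBR3, so that a change there was not measurable.

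Every one of the 35 S phase genes was lower in this difference between lines labelled FOXA1 siRNA (35 adjusted over the list alone; camera adjusted p = 9.15e-29). List medians were -1.33 in MCF7, -0.82 in T47D, -0.33 in MB453 and -0.08 in SKBR3. G2 and mitosis genes were lower in 35 of 36 cases (35 adjusted over the list alone; camera adjusted p = 5.70e-30). Oestrogen-induced genes were lower in 28 and higher in 0 of 35 (28 and 2 adjusted over the list alone; camera adjusted p = 3.77e-15). Luminal markers were lower in 15 and higher in 5 of 28 (16 and 5 adjusted over the list alone; camera adjusted p = 0.000179). Junction genes were higher in 8 and lower in 2 of 28 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000562) and p53 targets were higher in 11 and lower in 2 of 20 (13 and 2 adjusted over the list alone; camera adjusted p = 2.11e-05). Interferon genes were higher in 11 of 36 (11 adjusted over the list alone; camera adjusted p = 6.32e-06, adjusted p = 0.584 with an estimated correlation), with a median of 0.443 that lay between 0.251 and 0.809 over the alternatives. Unfolded protein genes were higher in 8 and lower in 1 of 20 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0378, adjusted p = 0.440 with an estimated correlation). Basal markers were higher in 6 and lower in 7 of 39 (6 and 11 adjusted over the list alone; camera adjusted p = 0.379). The difference passed for 5172 genes, 2265 higher and 2907 lower, 169 of them by at least 2-fold. Each side lay on slides of its own, and slide as a random block left 3408 genes. Median centring left 1764 (62.2% higher against 43.8%), ending the luminal call (median 0.08, adjusted p = 0.349) and that of ESR1 (-0.38). The unfolded protein call was lost with probes averaged per gene (adjusted p = 0.133), without MCF7 replicate 1 (adjusted p = 0.144), T47D replicate 1 (adjusted p = 0.0644) or replicate 2 (adjusted p = 0.0504) and without MB453 replicate 3 (adjusted p = 0.0862). With an estimated correlation 11 of the 38 list calls in the 4 lines, their mean and this difference held. They were those of the luminal, oestrogen-induced, S phase, G2 and mitosis and p53 lists in MCF7 and in this difference and that of the junction list in this difference.

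**Figure D3:**
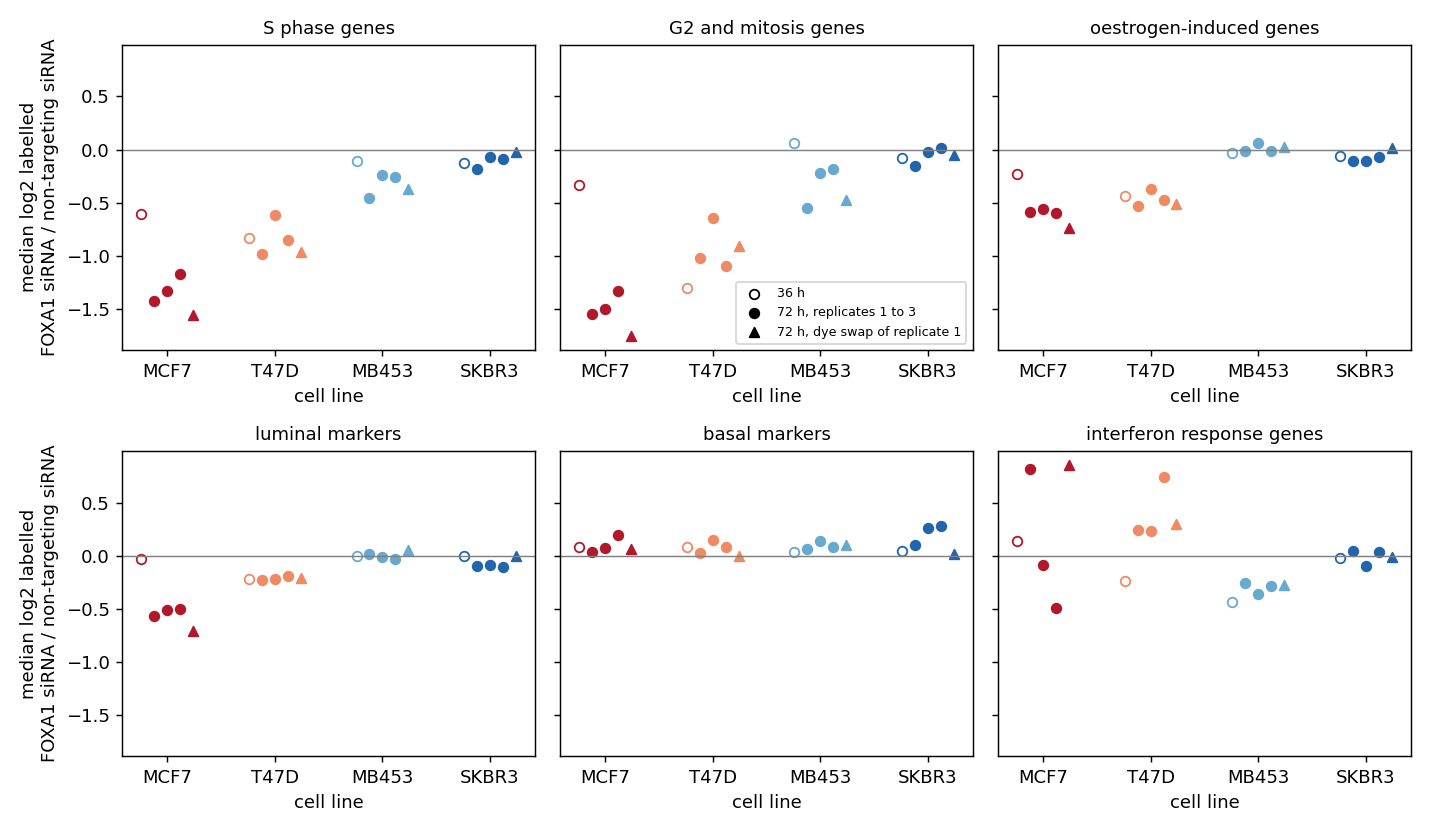
Median log2 ratio (labelled FOXA1 siRNA over non-targeting siRNA) of gene lists on each array at 36 h and 72 h, by line. The lists are S phase, G2 and mitosis, oestrogen-induced, luminal, basal and interferon response genes. The median over S phase genes of the line mean at 72 h was -1.33 in MCF7 and -0.08 in SKBR3.

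At 36 h, with 1 array per line and the spread taken from the 72 h replicates, ANXA1 was already higher in the mean of the 4 lines labelled FOXA1 siRNA, at 1.69 ± 0.29 (log2, SE). TYMS and PREX1 were lower, at -1.15 ± 0.08 and -1.31 ± 0.11. FOXA1 averaged 0.12 ± 0.09 at 36 h (limma adjusted p = 0.476). Between 36 h and 72 h CX3CR1 rose further by 1.04 ± 0.12, S100A8 by 0.86 ± 0.18, THRSP by 0.81 ± 0.12, the ubiquitin ligase gene FBXO32 by 0.75 ± 0.10 and N4BP2L1 by 0.69 ± 0.09. UGT2B11 fell further by 1.11 ± 0.11, its paralogue UGT2B15 by 0.75 ± 0.07, the PCNA-binding gene PCLAF by 0.70 ± 0.10, PTTG2, a near copy of PTTG1, by 0.66 ± 0.09 and the Wnt inhibitor gene DKK1 by 0.65 ± 0.08. At 36 h 2851 genes passed, 1371 higher and 1480 lower, while 770 differed between the times, 263 higher and 507 lower at 72 h. With only replicate 1 at 72 h fewer samples remain, and the change is tested against the spread between lines instead of that between replicates. In that fit limma called 0 genes for the difference in time (2769 at an unadjusted p under 0.05). The 10 genes named for it then had limma adjusted p-values between 0.278 and 0.336. CX3CR1 measured 0.99, S100A8 1.26, THRSP 0.84, FBXO32 0.875, N4BP2L1 0.71, UGT2B11 -1.11, UGT2B15 -0.77, PCLAF -0.65, PTTG2 -0.71 and DKK1 -0.67. Array 1 shared its slide with the 36 h array of its line, while its dye swap lay on another. With only array 1 limma also called 0 genes (1967 at an unadjusted p under 0.05), with the same mean changes by construction of the dye correction. The 770 became 12 with median centring, 29 without MCF7 (19 higher and 10 lower), 241 without MB453, 485 without MB453 replicate 2 and 1372 without SKBR3 replicate 1. The S100A8 call was lost in 7 settings, among them those without background subtraction (0.77), without MCF7 (0.97) and without MB453 (0.57). The UGT2B15, PCLAF, PTTG2 and DKK1 calls were lost without MCF7 (-0.33, -0.45, -0.39 and -0.52), and the THRSP, FBXO32, N4BP2L1, UGT2B15 and DKK1 calls under median centring (0.845, 0.80, 0.66, -0.76 and -0.87). The 2851 became 342 with median centring, 4399 without background subtraction, 4305 from Agilent's processed signals and 937 without T47D.

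**Figure D4:**
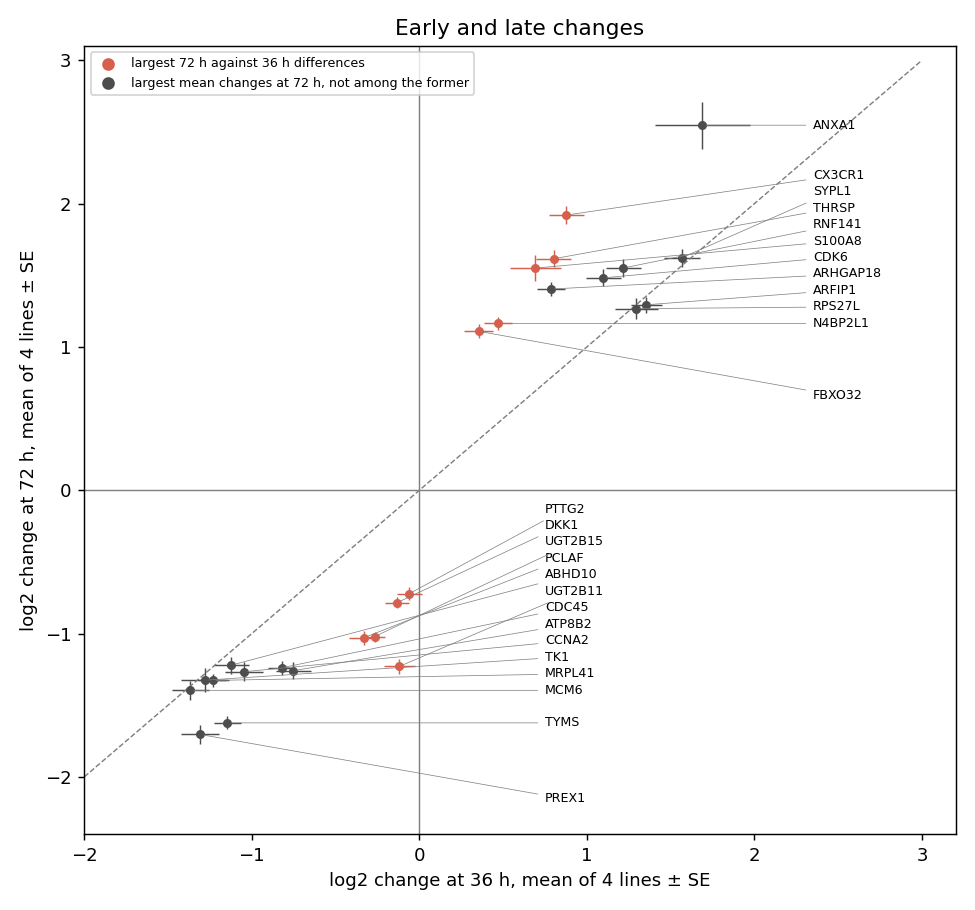
Mean log2 ratio of the 4 lines labelled FOXA1 siRNA at 72 h against that at 36 h, with SE on both axes and the line of equal change dashed. CX3CR1 differed between the times by 1.04 and UGT2B11 by -1.11.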

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

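The tests of exchanged dyes, of blind FOXA1 probes, of the second FOXA1 probe, of the non-targeting channel and of the MCF7 interferon replicates were chosen only after the results were seen, and the other tests were set beforehand.

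FOXA1 transcript differed between MCF7 and T47D on one side and MB453 and SKBR3 on the other by 0.79 ± 0.10 (log2, SE, limma adjusted p = 9.26e-05, between 2.13e-06 and 0.00163 over the alternatives), being above 0 against the label in 5 of 6 replicates of MCF7 and T47D. Exchanged dye labels would turn every change around, yet the lowest correlation over genes between a line of one side and a line of the other was 0.27 (highest 0.54, replicate 1 alone), which argues against it. Probes blind to the loss of FOXA1 in every line are excluded by MB453, where the 2 probes averaged -0.63 and -0.68. An error of the single spot of A_24_P347431 is excluded in MCF7 by the dimmer probe A_23_P37127, in 10 spots, which averaged 0.47 (95% interval over 3 replicates from 0.22 to 0.72). In T47D it averaged 0.28 (from -0.19 to 0.76), which leaves that error open there. A shift of the brightest spots left by the normalization would change sign on the dye swap if it followed the dye. Without the dye correction MCF7 measured 0.29 on array 1 and 0.50 on its swap at A_24_P347431, which argues against such a shift in MCF7. A shift that follows the labelled siRNA channel, which the swap cannot show, stays open. In T47D, with replicate 2 below 0, either kind stays open. The 200 genes closest in brightness had a median of 0 in MCF7 and -0.01 in T47D, which loess sets near 0. FOXA1 lay at their percentile 88.5 in MCF7 and 78.5 in T47D, which decides nothing, since their spread holds their own changes. A difference between the lines in FOXA1 response, and which of the 2 siRNAs each array received, also stay open and were not tested.

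S phase genes fell more in MCF7 and T47D than in MB453 and SKBR3, with a median difference of -0.818 (camera adjusted p = 9.15e-29, 0.0329 with an estimated correlation, between 8.99e-38 and 0.0329 over the alternatives). The spread between slides is argued against as the whole cause, since with slide as a random block 34 of 35 genes passed. Dimmer signals in MB453 and SKBR3 are excluded by the non-targeting channel, where these genes differed by -0.02 (log2, SD 0.58 over 35 genes). The mean of both channels (-0.46, SD 0.62) decides nothing, because the fall itself lowers it. A smaller response of all genes in MB453 and SKBR3 stays open, because the median ratio of the S phase genes' change between the sides, 0.19, lay at percentile 43.4 of the other genes that moved by at least 2-fold. The receptor class of the lines, which their slides share, also stays open and is untested with 2 lines a side.

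Interferon response genes differed between the replicates of MCF7, with list medians of 0.816 on array 1, 0.856 on its swap, -0.09 on array 2 and -0.493 on array 3. Noise of single arrays is excluded as the whole cause, since array 1 and its swap differed by 0.04 against a range of 1.329 over replicates. A scan day common to the lines is excluded as the whole cause. Replicate 1 minus the mean of replicates 2 and 3, scanned on other days, was 1.13 in MCF7 but -0.21 in T47D, 0.05 in MB453 and 0.05 in SKBR3 (mean of these -0.04, SD 0.15). A slide shared by MCF7 and T47D is argued against as the whole cause by MCF7 itself. Array 1 and its swap lay on separate slides and gave 0.816 and 0.856. Arrays 2 and 3 shared a slide and gave -0.09 and -0.493. A part played by the slide of arrays 2 and 3 stays open, with T47D alone to test it. T47D replicate 1, on the same slides, lay below the mean of its replicates 2 and 3, but only through replicate 3 (0.74). Against replicate 2 alone it lay higher by 0.04, and that of MCF7 by 0.93. Which of the 2 siRNAs each replicate received may matter and was not tested, and no biological explanation was tested.

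A single array lay far from the other 3 of its line in 3 of 64 groups of 4 arrays. Chance flags about 1 in 20 groups of 4 independent arrays. That rate need not hold here, since array 1 and its swap were read as the same RNA. The flagged values were the median of mesenchymal markers on the MB453 swap (-0.017, others between 0.04 and 0.047), of interferon genes on T47D replicate 3 (0.74, others between 0.236 and 0.303) and of hypoxia genes on MCF7 replicate 3 (-0.303, others between -0.055 and -0.009).

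Other lists also differed between the receptor classes by camera. Luminal markers differed by a median of -0.351 (adjusted p = 0.000179), junction genes by 0.136 (0.000562), oestrogen-induced genes by -0.638 (3.77e-15), G2 and mitosis genes by -0.95 (5.70e-30) and p53 targets by 0.347 (2.11e-05), with adjusted p-values of 0.0367, 0.0367, 0.00743, 0.0367 and 0.00894 with an estimated correlation. Interferon genes differed by 0.443 (6.32e-06) and unfolded protein genes by 0.091 (0.0378), but with adjusted p-values of 0.584 and 0.440 with an estimated correlation. The interferon difference lay between 0.251 (without MCF7 replicate 1) and 0.809 (median centring) over the alternatives, and lost its call only with the estimated correlation. List medians were 0.089 in MCF7, 0.408 in T47D (0.245 without its replicate 3), -0.264 in MB453 and -0.031 in SKBR3.

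Among single genes named whatever their result, limma found differences between the receptor classes in ESR1 (-1.25, adjusted p = 1.19e-07), AR (-0.74, 2.62e-06), GATA3 (0.45, 0.00436), KRT8 (0.36, 0.00817), KRT18 (0.37, 0.0495) and KRT14 (-0.32, 0.0215). ESR1 was not above the negative controls in MB453 or SKBR3, so its difference rests on MCF7 and T47D. The KRT18 difference lost its call in 14 of 26 alternatives (adjusted p up to 0.133), with values between 0.288 and 0.394 there, and the KRT14 difference in 4 of 26 (adjusted p up to 0.108), with values between -0.496 and -0.162.

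Outside the named genes, 5 of 12325 probes without a gene name passed at 2-fold or more in the mean of the lines at 72 h. The 153 negative control spots, tested spot by spot, were too few to compare at that bar, since this rate would give 0.06 of them. In all 4295 of these probes (34.8%) passed the threshold, and 1 negative control did.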

How the results depend on the processing

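The negative control filter, the fit without dye swaps, only array 1 at 72 h and slide as a fixed block were chosen after the data were seen, and the other settings were planned. Leaving out the void scanner-flag settings, counts of genes moved by over 1.5 times in 30 of 181 values, named genes lost their call in 500 of 10774 values and gained one in 64 (5 reversed), and list calls were lost in 42 of 1770 values and gained in 18. Of the 42 lost list calls, 27 came from the estimated correlation. The 1770 include lists without a call in the main fit, which could not lose one. Agilent's processed signals and the series matrix gave the same counts but enter as separate settings. Unless stated below, the cause was not tested.

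Median centring changed the counts to 4136 genes in MCF7 (64.5% higher against 48.7%), 3336 in T47D (36.4% against 46.5%), 839 in MB453 (39.8% against 54.0%), 931 in SKBR3 (33.3% against 46.7%), 5786 in the mean at 72 h (39.9% against 48.9%), 1764 between receptor classes (62.2% against 43.8%), 12 between times (16.7% against 34.2%) and 342 in the mean at 36 h (69.6% against 48.1%). It moved the median of all genes between times from -0.004 to -0.137. It turned EGFR in SKBR3 to 0.063, CDH1, FN1 and VWF between receptor classes to 0.3, 0.003 and -0.032, and ESR1 in the mean at 36 h to 0, none of them past the threshold.

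FOXA1 in SKBR3 lost its call with median centring (-0.441), probes averaged (-0.255), slide as a random block (-0.323) or a fixed block (-0.329) and the line alone (-0.318), with adjusted p between 0.0215 and 0.303 over all alternatives. In each of the 4 lines and between receptor classes FOXA1 kept its sign in each alternative.

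The 36 h mean gave 4399 genes without background subtraction, 4305 from Agilent's processed signals and from the series matrix, and 937 without T47D (61.5% higher against 48.1%). The difference between times gave 0 genes with only replicate 1 at 72 h (2769 at an unadjusted p under 0.05 by limma). It also gave 0 with only array 1, which lay on the slide of the 36 h array (1967 at an unadjusted p under 0.05 by limma). Both fits have fewer samples and test against the spread between lines instead of that between replicates. The count was 29 without MCF7 (65.5% higher against 34.2%) and 241 without MB453 (22.8%). Slide as a random block left 3408 genes between receptor classes, and SKBR3 alone gave 2112. A 2-fold minimum, smaller by construction, left 547 genes in MCF7, 402 in T47D, 95 in MB453, 78 in SKBR3, 72 in the mean at 72 h and 169 between receptor classes. With an estimated correlation 11 of 38 list calls held.

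Leaving out 1 replicate gave between 5862 and 6272 genes in MCF7, 6152 and 6926 in T47D, 2507 and 2825 in MB453, 1734 and 5053 in SKBR3, 9046 and 10692 in the mean, 4318 and 5384 between receptor classes, and 485 and 1372 between times. FOXA1 then lay between 0.343 and 0.446 in MCF7, 0.053 and 0.338 in T47D, -0.792 and -0.553 in MB453, -0.408 and -0.24 in SKBR3, and 0.725 and 0.868 between receptor classes. The interferon list in MCF7, with no call on all replicates, then lay between -0.336 (without replicate 1, adjusted p = 0.00886) and 0.384 (without replicate 3), with adjusted p between 0.00229 and 0.933 over the alternatives.

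Whether replicate numbers pair the samples stays open. Deviations from line means correlated more between same-numbered replicates than between others in 16 of 18 cases. Such deviations cancel within a line, so a positive correlation for one number lowers the others. Array 1 was also scanned on another day than arrays 2 and 3 in every line. Correlations between same-numbered replicates were over 0.1 in 11 of 18 cases (lowest -0.076, highest 0.494), with all 3 over 0.1 in 2 of 6 pairs of lines, MCF7 with MB453 and T47D with MB453. With the replicate block 7635 genes passed in MCF7, 8357 in T47D, 4836 in MB453, 4612 in SKBR3, 10488 in the mean and 5699 between receptor classes, FOXA1 in SKBR3 (-0.318, adjusted p = 0.0555) and 1 other named gene lost their call, 2 gained one, and no list call changed. Signals of 1.61 to 2.92 times the negative controls in green limit what dim genes can show.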

Other observations

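The splits of the samples were set beforehand except that of whole lines in the mean at 72 h, which was chosen after the results were seen, and the genes named here were chosen after their values were seen.

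With signs of replicates turned at random, or samples regrouped, the real grouping gave the most genes among the splits run in each comparison (1 split each, the real one, gave as many). In the mean of the lines at 72 h, where 100 of 2048 splits were drawn, the real 9850 genes stood against at most 6455, which excludes chance signs of the replicates with no change in any line. It does not exclude lines that change in opposite ways. With whole lines turned the highest other was 7905, and 8 splits are too few for a share under 0.05. Between times 770 stood against at most 463 (100 of 256 drawn), which excludes a random regrouping but not slide or scan day. The 36 h arrays shared both with array 1, whereas replicates 2 and 3 lay on another slide and day. With slide as a fixed block, which counts replicate 1 to the slide of array 1, 803 genes passed and 439 of the 770 were shared in direction. Between 6 and 6 replicates of the receptor classes, fitted without a mean per line, 2729 genes stood against at most 203 (100 of 462 drawn). That test is void, because replicates of a line resemble each other and splits that part a line must give few genes. Splits were too few for a share under 0.05 in MCF7 (7204 genes, highest other 2), T47D (7666, 2), MB453 (4223, 0) and SKBR3 (4101, 1) with 4 each, in the difference between whole lines with 3 (5172, highest other 3662) and in the mean at 36 h with 8 (2851, 1402).

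Several genes had nearly the same mean change at 36 h as at 72 h, among them SYPL1 (1.57 and 1.62), ARFIP1 (1.36 and 1.29), RPS27L (1.30 and 1.27), MCM6 (-1.37 and -1.40), TK1 (-1.28 and -1.32), MRPL41 (-1.23 and -1.33) and ABHD10 (-1.12 and -1.22). UGT2B11 was at -0.12 at 36 h and -1.23 at 72 h. In SKBR3 at 36 h MCM6 measured -1.20 while the median of the S phase genes was -0.125.

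PREX1 measured -2.48 in MCF7, -1.99 in T47D and -2.06 in SKBR3 but -0.29 in MB453 (limma adjusted p = 0.14). UGT2B11 fell in each line, by 1.82 in MCF7, 1.20 in T47D, 1.20 in MB453 and 0.70 in SKBR3, whereas AR measured -0.89, -0.93, 0.30 and -0.64 in the same order. HMGCS1 measured 0.60 in MCF7, 0.95 in T47D and 0.88 in MB453, although more genes of the cholesterol list fell than rose in each line. CLDN3 was higher and ESRP2 lower in each line, although both are in the junction list. The control genes FOXA2 (in MB453 and SKBR3) and KRT5 (in MCF7, T47D and MB453) were not above the negative controls in either channel. Values of EGFR were -0.05, -0.20, 0.06 and -0.22 in MCF7, T47D, MB453 and SKBR3, those of ERBB2 0.52, 0.01, 0.29 and 0.12, and those of FOXA3 -0.06, -0.40, -0.07 and -0.33, past the threshold for EGFR in T47D and SKBR3, ERBB2 in MCF7 and FOXA3 in T47D and SKBR3.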
